A study of Homo sapiens with 15 samples.

How the data were processed

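Total RNA from 9 HEK293T and 6 HuCCT1 libraries was sequenced on a HiSeq2000 with a strand-specific Illumina kit that depletes ribosomal RNA. The authors deposited a table of counts per gene for each line, whole numbers without normalization, and these counts are the unit of every value used here. The labels name cutadapt 4.2, HISAT2 2.2.1 and RSEM with the human build hg38, and state neither their roles nor the gene annotation release. Gene identifiers, symbols, types and coordinates stand in the tables and were used as given. The HEK293T table held 62703 genes, 22008 of them without a count in any library. The HuCCT1 table held 35595 genes, none of them without a count, and all of its 35595 identifiers stood in the HEK293T table. HEK293T libraries had no count on any mitochondrially encoded gene, so those genes were compared in HuCCT1 alone.

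Total counts ran from 7944276 to 11270267 in HEK293T and from 13776166 to 16795618 in HuCCT1. A floor of 3 counts, the upper limit that a count of 0 allows, equals 0.266 to 0.378 CPM in single HEK293T libraries. Counting intervals are exact at 95% confidence, and intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Between replicates the spread exceeded counting error, with a chi-square per degree of freedom of 3.42 to 12.9 over pairs of libraries in a group.

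Groups were taken from the sample labels. Each line was fitted on its own in R 4.3.3 with edgeR 4.0.16, using TMM factors, the default low-count filter (minimum count 10, minimum total 15) and the quasi-likelihood F test. The fit for HEK293T held all 9 libraries, and 15882 genes were tested there and 15007 in HuCCT1. The biological coefficient of variation was 10.8% and 10.1%. p values were adjusted by Benjamini and Hochberg within each comparison, two-sided, at a threshold of 0.05. Log2 fold changes are first group minus second as labelled, with standard errors from the model, and CPM are scaled by the TMM factors. The difference between the lines in the SNRPD2KO response was tested as an interaction over the 12 SNRPD2KO and Ctrl libraries in 1 fit on the shared genes.

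Named genes were the 10 with the largest fold change in each direction that passed the threshold, had at least 5 CPM on average in the higher group, did not overlap between groups and carried a proper gene symbol. The target genes, up to 4 members per list the 5 strongest shared genes and the 5 largest differences between the lines per direction were added. SLC3A2 and ISG20 in the HEK293T lists were named outside this rule, after their values were seen. Some genes that met the rule were left out of the text. The 29 gene lists cover splicing factors, pseudouridine synthases, stress responses, cell cycle, metabolism, signalling and cell type markers. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with a correlation estimated per list. The first test asks whether members move differently from other genes. Members significant after adjustment over the list alone were counted beside those over all genes, and SNRPD2 was left out of its own list. Of the camera calls, 1, 1, 0 and 8 held with an estimated correlation, out of 9, 10, 3 and 19 in the 3 HEK293T comparisons and in HuCCT1. Genes were also grouped by the intron number of their longest-spliced transcript in the GENCODE 29 basic annotation, known for 97.0% and 97.1% of tested genes, and tested the same way.

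Comparisons, lists, the rule for named genes and most alternatives were fixed before the data were examined. Those alternatives were RLE and upper quartile factors, other filters, limma voom, DESeq2 1.42.0, a test against 1.5-fold, an adjusted p under 0.01, a replicate block, the 2 groups alone in the fit and each library left out. Removing a per-library trend with transcript GC content, thinning all libraries of a line to its smallest total, robust dispersions and further settings for the intron classes were added after the data had been seen. The pipeline was tested on simulated counts: of genes set to 2-fold it recovered 68.7% to 76.1% in single comparisons and 38.8% in the interaction, and it called the raised list in all 4. With a simulated GC trend and no difference, it called 4115 genes without the GC offset and 2 with it. In the other simulations 66 or 67 genes changed per fold, or 1 list was raised, and genes were drawn independently. List calls among genes that move together, or with many genes changed, were therefore not tested by simulation. Splicing itself was not measured, since the tables hold counts per gene and no junctions or introns.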

Results

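RNA sequencing measured gene expression in 15 libraries from 2 established human cell lines, after ribosomal RNA had been removed from total RNA. The HEK293T line comes from embryonic kidney and carries a viral large T antigen. HuCCT1 is a cholangiocarcinoma line, a cancer of the bile duct. The labels name 3 libraries each of HEK293T SNRPD2KO, HEK293T PUS7KO, HEK293T Ctrl, HuCCT1 SNRPD2KO and HuCCT1 Ctrl, where KO stands for knockout and Ctrl for control. SNRPD2 encodes SMD2, a protein of the Sm ring around the spliceosomal small nuclear RNAs, and PUS7 encodes an enzyme that turns uridines of RNA into pseudouridines. Total counts were 10080682 to 11270267 in the HEK293T SNRPD2KO libraries, 10022912 to 11181703 in PUS7KO, and 7944276 to 9202622 in Ctrl. In HuCCT1 they were 15580342 to 16772238 in SNRPD2KO and 13776166 to 16795618 in Ctrl. Group names are those of the labels throughout, and SNRPD2 RNA went against those names in both lines.

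The first question was whether each target gene was lower in the libraries labelled as its knockout. PUS7 (ENSG00000091127.14, chromosome 7, 105439661 to 105522271, build hg38) was lower in HEK293T PUS7KO, at 16.04 ± 2.24 CPM (counts scaled to the library total; SD, n = 3), against 26.5 ± 0.510 in Ctrl. Its log2 fold change was -0.72 with a standard error of 0.11 (adjusted p = 6.7e-05). SNRPD2 (ENSG00000125743.11, chromosome 19, 45687460 to 45692569) was higher in the libraries labelled SNRPD2KO in both lines. In HEK293T it stood at 280.4 ± 31.9 CPM (SD, n = 3) in SNRPD2KO and 182 ± 13.6 in Ctrl, a log2 fold change of 0.62 with a standard error of 0.10 (adjusted p = 4.9e-05). In HuCCT1 it stood at 288 ± 29.4 CPM against 155 ± 7.30, a log2 fold change of 0.90 with a standard error of 0.07 (adjusted p = 1.8e-06). Every library labelled SNRPD2KO lay above every Ctrl library in both lines. HEK293T PUS7KO libraries held 261 ± 22.6 CPM of SNRPD2, also above Ctrl (log2 fold change 0.52, adjusted p = 0.00034), and the difference between SNRPD2KO and PUS7KO did not pass (0.11, adjusted p = 0.56). The 2 lines did not differ in the SNRPD2 change by the test of the difference (0.23, HuCCT1 minus HEK293T, adjusted p = 0.16). PUS7 between SNRPD2KO and Ctrl gave 0.26 in HEK293T (adjusted p = 0.053) and 0.10 in HuCCT1 (adjusted p = 0.34), neither past the threshold. Gene counts do not show a small deletion that leaves the RNA in place, so these values measure RNA level alone.

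**Figure D1:**
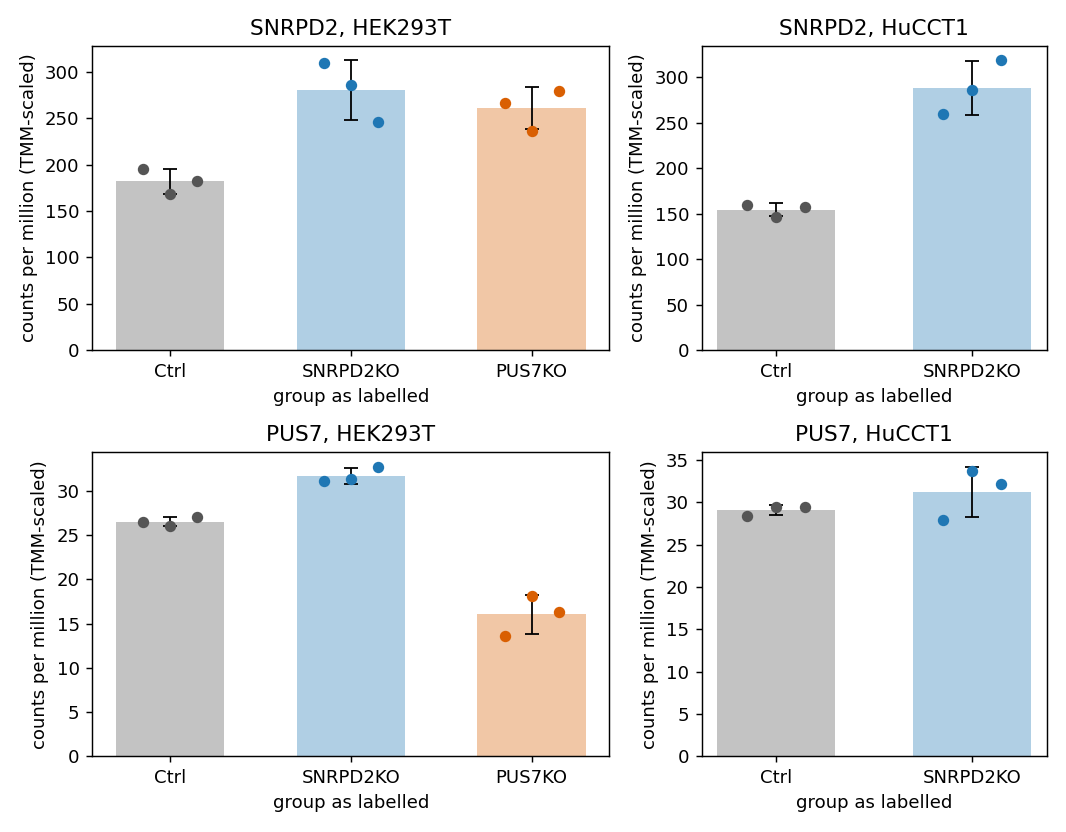
SNRPD2 and PUS7 level in CPM by group as labelled, with bars for the mean, lines for 1 SD and points for the 3 libraries of each group. SNRPD2 is higher in the libraries labelled SNRPD2KO than in Ctrl in both lines, and PUS7 is lowest in HEK293T PUS7KO at 16.04 CPM.

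Across the genome, the HEK293T SNRPD2KO and PUS7KO libraries lay together and away from Ctrl. Pairs of SNRPD2KO and PUS7KO libraries had correlations of log2 CPM of 0.973 to 0.984, close to the 0.979 to 0.985 within groups. Ctrl libraries gave 0.920 to 0.941 with SNRPD2KO and 0.929 to 0.944 with PUS7KO. HuCCT1 libraries gave 0.987 to 0.989 within groups and 0.953 to 0.957 between groups. These correlations run across genes, which are not independent replicates. More genes had a count in the HEK293T Ctrl libraries (29551 to 30073) than in SNRPD2KO (24947 to 26998) or PUS7KO (26626 to 27460), although Ctrl had the smallest totals. Small noncoding RNAs took 28.2% to 35.7% of HEK293T counts, with RN7SL1, the RNA of the signal recognition particle, alone at 15.2% to 20.5%. In HuCCT1, small noncoding RNAs and mitochondrially encoded genes together took 3.39% to 5.67%. Mitochondrially encoded genes alone took 0.866% to 1.76% there, so the share of small noncoding RNAs was lower than these totals.

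**Figure D2:**
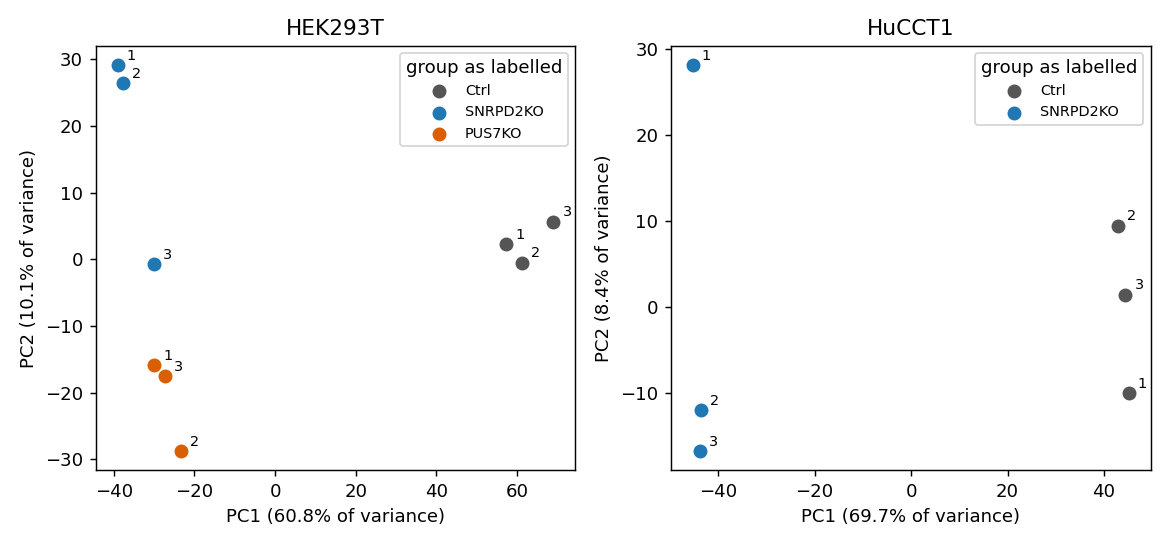
First and second principal components of log2 CPM for HEK293T (60.8% and 10.1% of variance) and HuCCT1 (69.7% and 8.4%), each point a library coloured by group as labelled. In HEK293T the SNRPD2KO and PUS7KO libraries lie together on the first component, apart from Ctrl.

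In HEK293T, the comparison of SNRPD2KO with Ctrl asked which genes differ with loss of SMD2. Integrated stress response genes rose in SNRPD2KO, in 26 of 29 members. The DNA replication, histone and interferon lists also passed upward, and SR splicing factors and p53 targets downward. Those 5 calls were lost in the stricter test (in that order, adjusted p = 0.197, 0.615, 0.197, 0.197 and 0.354 with an estimated correlation). INHBE (ENSG00000139269.3, chromosome 12, 57452323 to 57459280), which encodes the inhibin beta E subunit, rose most among genes of at least 5 CPM, from 2.64 ± 0.254 to 52.3 ± 7.60 CPM (SD, n = 3; adjusted p = 2.3e-11). ASS1, the argininosuccinate synthase of arginine synthesis, went from 22.1 ± 4.99 to 156 ± 8.13 CPM. Since SNRPD2 itself went against the label, each direction is that of the labelled groups and not of the SNRPD2 level. Of 15882 genes tested, 8467 changed, 4276 higher and 4191 lower in SNRPD2KO, and 2785 of them by more than 2-fold. The groups did not overlap for 59.5% of genes, where chance gives 10%.

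After INHBE, the 10 genes above that level that rose most in SNRPD2KO held LINC02985 (log2 fold change 4.0), a noncoding RNA, CYFIP1 (3.87), which acts in actin and translation control, FUT1 (3.48), a fucosyltransferase, and G0S2 (3.47), an inhibitor of lipolysis. AKNA (2.89), a centrosome-associated protein, ASS1 (2.82), SLC7A3 (2.61), a transporter of cationic amino acids, PCK2 (2.58), the mitochondrial phosphoenolpyruvate carboxykinase, and STUM (2.53) completed them. CYFIP1 varied between the SNRPD2KO libraries, at 6.24 ± 5.08 CPM. Those that fell most were CPA4 (-5.50), a carboxypeptidase, TRIM72, a membrane repair protein of muscle, NPR3 (-5.12), the natriuretic peptide clearance receptor, CFAP45 (-4.56), a ciliary protein, and HSPA6 (-4.48), an inducible heat shock protein. FAM20A (-4.43), a protein of enamel formation, ADAMTSL4 (-4.0), AOC3 (-3.95), an amine oxidase, EMP1 (-3.74), a membrane protein, and N4BP2L2-IT2 (-3.66) followed. TRIM72 had 4 counts in SNRPD2KO and 144 in Ctrl, a CPM ratio of 40.3 with a 95% counting interval of 15.4 to 150.1.

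Integrated stress response genes rose in 26 of 29 and 1, SLC3A2 (-0.35), fell, also adjusted over the list alone. Their median was 1.05 (adjusted p of the list test 2.1e-09, and adjusted p = 0.0094 with an estimated correlation). TRIB3 (2.50), a pseudokinase induced by ATF4, CTH (2.29), of cysteine synthesis, SHMT2 (2.15), of serine and folate metabolism, and PSAT1 (1.61), of serine synthesis, were among them. SR proteins and their kinases, which select splice sites, fell in 27 of 31 and rose in 2, with the same counts adjusted over the list alone (median -0.73, adjusted p = 6.0e-08). That call was lost in the stricter form of the test (adjusted p = 0.197 with an estimated correlation). LUC7L3 (-1.88), a U1-associated factor, SRSF6 (-1.50), RSRC2 (-1.48) and SRSF1 (-1.17) fell. DNA replication genes rose in 32 of 40, with 33 adjusted over the list alone and none lower (median 0.46, adjusted p = 7.4e-08, and adjusted p = 0.197 with an estimated correlation). CDC45 (1.37), MCM7 (1.31) and MCM3 (1.12), of the replicative helicase, and E2F1 (1.22), a transcription factor of S phase, rose. Replication-dependent histone genes rose in 36 of 43 with none lower, and in 36 adjusted over the list alone (median 0.74, adjusted p = 1.2e-07, and adjusted p = 0.615 with an estimated correlation). H2AC15 (1.36), H2AC13 (1.29) and H2AC6 (1.20), of the H2A family, were examples.

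p53 targets fell in 19 of 29 and rose in 6, with 20 lower and 6 higher adjusted over the list alone (median -0.69, adjusted p = 0.0049, and adjusted p = 0.354 with an estimated correlation). ZMAT3 (-1.70), GDF15 (-1.66), a stress cytokine, TIGAR (-1.44) and MDM2 (-1.31), the p53 ubiquitin ligase, fell. Interferon response genes rose in 12 of 18 and 1, ISG20 (-0.94), fell, with 13 and 1 adjusted over the list alone (median 0.90, adjusted p = 0.0057, and adjusted p = 0.197 with an estimated correlation). IFI6 (2.12), USP18 (1.01), IFIT1 (0.98) and STAT2 (0.71) rose. Ribosomal protein genes rose in 40 of 75 and fell in 6, with 41 and 6 adjusted over the list alone (median 0.24, adjusted p = 0.0148, and adjusted p = 0.807 with an estimated correlation). RPLP0 (1.03) and RPL13 (0.76) rose. Immediate early genes, induced within minutes of a stimulus, fell in 15 of 31 and rose in 6, with the same counts adjusted over the list alone (median -0.38, adjusted p = 0.0329, and adjusted p = 0.417 with an estimated correlation). Among these CCN2 (-2.02) and FOSL2 (-1.70) fell while MYC (1.94) and JUND (1.14) rose, and the list did not pass without SNRPD2KO replicate 3 (adjusted p = 0.0990) or Ctrl replicate 1 (0.0631), where alternatives ran from 0.00053 to 0.417.

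Splicing genes other than SR factors moved both ways. Of 61 spliceosome subunits 27 fell and 13 rose (median -0.17, adjusted p = 0.0934, and 0.0395 with a trend in GC content removed, with 0.0018 to 0.615 over the alternatives), with DDX46 (-1.74) and SF3B1 (-1.18), both of the U2 particle, lower and SNRPA (1.10), a U1 protein, higher. Of 15 Sm and LSm proteins, SNRPD2 left out, 7 fell and 3 rose (median -0.23, but 0.12 with the GC trend removed, adjusted p = 0.232). LSM3 (-1.18) and SNRPB (-0.52) fell and LSM7 (0.68) rose. Pseudouridine synthases and H/ACA proteins, which make pseudouridines, rose in 8 of 18 and fell in 6 (median 0.26, adjusted p = 0.376). With the GC trend removed their median was 0.06. RPUSD3 (1.63) and DKC1 (0.66) were higher and TRUB1 (-0.79) lower. Genes grouped by their number of introns gave no class past the threshold, with medians between -0.07 and 0.08. The GC content of transcripts correlated across genes with the fold change (Spearman rho 0.36), and the ribosomal protein call was lost with that trend removed (adjusted p = 0.167). DNA repair (0.0227), hypoxia and glycolysis (0.0395) and cholesterol synthesis genes (0.0453) did not pass with the trend kept and passed with it removed.

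Between PUS7KO and Ctrl in HEK293T, the question was which genes differ with loss of the pseudouridine synthase. Integrated stress response genes rose in PUS7KO, in 27 of 29 members. The DNA replication list also passed upward, and SR factors, spliceosome subunits and p53 targets downward. Those 4 calls were lost in the stricter test (in that order, adjusted p = 0.278, 0.243, 0.356 and 0.294 with an estimated correlation). G0S2 rose by 4.27 and INHBE by 4.41 on the log2 scale, and PUS7 itself was lower. The same 3 Ctrl libraries served in both HEK293T comparisons. Between SNRPD2KO and PUS7KO, the stress response, SR, p53 and DNA replication lists did not pass (adjusted p = 0.918, 0.761, 0.861 and 0.156). Spliceosome subunits did (0.0295). If the SNRPD2KO and Ctrl labels were exchanged, the contrast of PUS7KO with control would be that of the libraries labelled PUS7KO and SNRPD2KO. The changes here can therefore not be assigned to loss of PUS7. Of 15882 genes 7839 changed, 4063 higher and 3776 lower, and 2316 by more than 2-fold. The groups did not overlap for 57.2% of genes, where chance gives 10%.

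Under the same limit of 5 CPM, the strongest rises after INHBE and G0S2 in PUS7KO were FUT1 (3.64), AKNA (3.07), MZT2B (3.07), a protein of the gamma-tubulin ring, ASS1 (2.95), PCK2 (2.95), CALCB (2.55), a calcitonin-related peptide, SLC7A3 (2.54) and ALDH1L2 (2.50), a mitochondrial folate enzyme. MZT2B rested on PUS7KO replicate 2, without which it gave 1.23 (adjusted p = 0.078, with 0.00056 to 0.078 over the alternatives). The strongest falls were TRIM72, NPR3 (-5.55), CPA4 (-4.34), CFAP45 (-4.01), ETV4 (-3.86), an ETS transcription factor, CMYA5 (-3.62), FAM20A (-3.56), CD200R1 (-3.55), an inhibitory receptor, ABCC2 (-3.48), an export pump for conjugates, and ADAMTSL4 (-3.46). TRIM72 had 2 counts in PUS7KO against 144 in Ctrl, a CPM ratio of 85.8 with a 95% counting interval of 23.3 to 716.

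Integrated stress response genes rose in 27 of 29 and 1, again SLC3A2 (-0.62), fell, also adjusted over the list alone (median 1.11, adjusted p = 1.9e-11, and adjusted p = 0.0055 with an estimated correlation). TRIB3 (2.50), CTH (2.18), SHMT2 (2.09) and PSAT1 (1.62) led. SR proteins and kinases fell in 26 of 31 and 1 rose, with 27 and 1 adjusted over the list alone (median -0.64, adjusted p = 3.6e-08, and adjusted p = 0.243 with an estimated correlation). SRSF6 (-1.63), LUC7L3 (-1.55), TRA2A (-1.46) and SRSF1 (-1.29) fell. Spliceosome subunits fell in 33 of 61 and rose in 11, with 34 and 12 adjusted over the list alone (median -0.29, adjusted p = 0.0020, and adjusted p = 0.356 with an estimated correlation). PRPF3 (-1.44) and PRPF4 (-1.0), of the U4/U6 particle, RBM22 (-1.21) and SF3B1 (-1.15) were lower. Nonsense-mediated decay factors, which clear RNAs with early stop codons, fell in 11 of 20 and 1 rose, with 12 and 1 adjusted over the list alone (median -0.27, adjusted p = 0.0172, and adjusted p = 0.294 with an estimated correlation). EIF4A3 (-2.34), of the exon junction complex, and SMG8 (-0.90) fell. DNA replication genes rose in 32 of 40 with none lower, also adjusted over the list alone (median 0.44, adjusted p = 9.6e-08, and adjusted p = 0.278 with an estimated correlation), RRM2 (1.23) and MCM7 (1.11) among them.

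Ribosomal protein genes rose in 38 of 75 and fell in 3, also adjusted over the list alone (median 0.23, adjusted p = 0.00080, and adjusted p = 0.761 with an estimated correlation), with RPLP0 (1.02) and RPL13 (0.69) higher. p53 targets fell in 17 of 29 and rose in 5, with 17 and 6 adjusted over the list alone (median -0.58, adjusted p = 0.0014, and adjusted p = 0.294 with an estimated correlation). PHLDA3 (-1.52), TIGAR (-1.49) and GDF15 (-1.32) fell. Histone genes rose in 20 of 43 and fell in 2, with 22 and 2 adjusted over the list alone (median 0.32, adjusted p = 0.0140, and adjusted p = 0.761 with an estimated correlation), such as H2AC15 (1.02). Mitotic genes fell in 21 of 46 and rose in 5, also adjusted over the list alone (median -0.20, adjusted p = 0.0216, and adjusted p = 0.294 with an estimated correlation). SGO2 (-1.61), which guards centromere cohesion, CENPE (-1.12) and TTK (-0.81) were lower. Immediate early genes fell in 15 of 31 and rose in 6, with 17 and 6 adjusted over the list alone (median -0.31, adjusted p = 0.0313, and adjusted p = 0.356 with an estimated correlation), with CCN2 (-2.05) lower and MYC (1.81) and JUN (1.18) higher. Removing the GC trend lost the histone call (adjusted p = 0.0747). The mitotic call was lost without PUS7KO replicate 1 (0.0598, with 0.00040 to 0.294 over the alternatives), and the immediate early call without PUS7KO replicate 2 (0.0879) or Ctrl replicate 1 (0.0640, with 0.00040 to 0.356 over the alternatives).

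Most genes that changed in one HEK293T comparison changed alike in the other. Genes higher in both numbered 3363, where independent calls would give 1094, and genes lower in both 3131, where they would give 996.4. Another 5 genes, named here after their values were seen, changed in opposite directions. PSME2 (0.61 and -0.47), ARFIP2 (0.30 and -0.28) and H2AC4 (0.38 and -0.43) rose in SNRPD2KO and fell in PUS7KO, and EDIL3 (-0.37 and 0.49) and ELMOD2 (-0.29 and 0.28) the reverse. Fold changes correlated across genes with r = 0.90, and genes are not independent replicates. Sharing the Ctrl libraries raises such a correlation, so counts with no difference in any group were simulated 40 times with a common Ctrl group, which gave r = 0.523 on average, from 0.499 to 0.544. The covariance of the fold changes was 0.662 against 0.0388 in the simulated counts.

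Set directly against each other, the HEK293T SNRPD2KO and PUS7KO libraries differed in 758 of 15882 genes, 249 higher and 509 lower in SNRPD2KO, with 54 by more than 2-fold. PUS7 was higher in SNRPD2KO by 0.98 (31.7 ± 0.891 against 16.04 ± 2.24 CPM; SD, n = 3; adjusted p = 0.0018). Of 43 histone genes 15 were higher in SNRPD2KO, and of 18 interferon response genes 3. Both lists passed upward, but not in the stricter test (adjusted p = 0.866 and 0.153 with an estimated correlation). RPS2 (chromosome 16, 1962058 to 1964841), a protein of the small ribosomal subunit, was lower in SNRPD2KO, at 8.07 ± 1.53 CPM against 127 ± 29.2. The groups did not overlap for 25.2% of genes, where chance gives 10%.

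Among genes of at least 5 CPM, WDR73 (4.30), a WD repeat protein, rose most in SNRPD2KO, at 23.6 ± 18.2 CPM against 1.21 ± 0.330. LINC02985 (1.97), IFI6 (1.45), COG5 (1.38), a Golgi tether subunit, SCRIB (1.12), a cell polarity protein, UPK3BL2 (1.12), IFIT1 (1.09), PSME2 (1.07), a proteasome activator, and OAS3 (1.04) followed, the last an interferon-induced sensor of double-stranded RNA. After RPS2 (-3.96), the lower genes included MZT2B (-2.64, and -0.78 without PUS7KO replicate 2), HSPA6 (-1.88), ATP6V0D2 (-1.47), a proton pump subunit, SNX10 (-1.30), MALAT1 (-1.29), a nuclear noncoding RNA, INHBA (-1.27), the activin A subunit, RCC2 (-1.24) and OSTN (-1.17). Of the genes in these lists, the calls of WDR73, IFI6, IFIT1 and RPS2 held in all 9 settings tried for single genes and the others were lost in at least 1. LINC02985, for example, gave 4.16 without PUS7KO replicate 2 and lost its call without SNRPD2KO replicate 1 or 2 or PUS7KO replicate 1 or 3 (adjusted p up to 0.151, from 5.1e-05), and COG5 lost its call without any 1 library but PUS7KO replicate 3 (up to 0.0995, from 0.0018). Of 43 histone genes 15 rose, and 32 adjusted over the list alone, with none lower (median 0.41, adjusted p = 9.9e-12, and adjusted p = 0.866 with an estimated correlation), such as H2AC4 (0.81) and H2BC4 (0.58). Of 18 interferon response genes IFI6, IFIT1 and OAS3 rose, and 6 adjusted over the list alone, with none lower (median 0.40, adjusted p = 1.9e-05, and adjusted p = 0.153 with an estimated correlation). Spliceosome subunits passed upward with a median of 0.12 (adjusted p = 0.0295, and adjusted p = 0.866 with an estimated correlation), although the 2 members of 61 that changed were lower, SF3B6 (-0.35) among them, also adjusted over the list alone. That list did not pass without SNRPD2KO replicate 1 (0.0979) or PUS7KO replicate 2 (0.0562) or 3 (0.0566), with 0.0036 to 0.866 over the alternatives. Among 17 pseudouridine synthases and H/ACA proteins 4 changed upward and 2 downward (adjusted p = 0.100, and 0.0283 with the GC trend removed), with RPUSD1 (0.61) and PUS1 (0.56) higher and PUS7L (-0.89), a relative of PUS7, and TRUB1 (-0.63) lower.

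The count of 758 depended on single libraries. It was 22 without SNRPD2KO replicate 1, 29 without replicate 2 and 1891 without replicate 3, and 285, 32 and 662 without PUS7KO replicates 1, 2 and 3, and 117 with the GC trend removed (Spearman rho of GC with fold change across genes 0.49).

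In HuCCT1, the SNRPD2KO and Ctrl libraries posed the SMD2 question in cancer cells. Cholesterol synthesis genes rose in SNRPD2KO, while inflammatory signalling genes, spliceosome subunits, SR factors, heat shock genes and integrated stress response genes fell. These 6 list calls held with an estimated correlation (adjusted p = 0.0356 to 0.0443). INSIG1 (ENSG00000186480.13, chromosome 7, 155297776 to 155310235), a sterol sensor of the endoplasmic reticulum, rose from 13.3 ± 0.206 to 178 ± 12.3 CPM (SD, n = 3; adjusted p = 2.8e-10). SCD, the stearoyl-CoA desaturase, rose from 190.3 ± 9.28 to 1749 ± 27.7 CPM. SNRPD2 was higher in SNRPD2KO here too, so directions are again those of the labelled groups. Of 15007 genes tested 8591 changed, 4327 higher and 4264 lower, and 2212 by more than 2-fold. The groups did not overlap for 63.5% of genes, where chance gives 10%.

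After INSIG1 (3.74), the strongest rises included LRRN1 (3.60), a membrane protein of neurons, SCD (3.20), UACA (3.16), LSS (3.08), the lanosterol synthase, LINC02009 (2.89), TPR (2.86), a nuclear pore protein, MIR205HG (2.86) and ACSS2 (2.86), an acetyl-CoA synthetase. The largest falls were EEF1B2 (-6.47), a translation elongation factor, PSME1 (-4.43), DUSP14 (-4.43), a phosphatase, HBE1 (-4.20), a globin gene that overlaps HBG2, NME1-NME2 (-3.48), TFF1 (-3.39), a mucosal peptide, GUCA1B (-3.32), PI3 (-3.28), the elastase inhibitor elafin, MMP1 (-3.18), a collagenase, and SPRR2A (-3.08). Without Ctrl replicate 1, EEF1B2 gave -0.65 (adjusted p = 0.0619) and PSME1 -0.49 (0.204), and without SNRPD2KO replicate 2 PSME1 gave -4.42 (0.0540), with 0.0021 to 0.0619 for EEF1B2 and 0.0030 to 0.204 for PSME1 over the alternatives. DUSP14 was uneven between Ctrl libraries, at 8.30 ± 11.3 CPM, and went down to -2.25 in size over the alternatives.

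Cholesterol synthesis genes rose in 24 of 25 with none lower, also adjusted over the list alone (median 1.41, adjusted p = 6.4e-11, and adjusted p = 0.0356 with an estimated correlation), HMGCS1 (1.72) and FDPS (1.67) of the mevalonate pathway among them. Inflammatory signalling genes fell in 21 of 23 with none higher, and in 22 adjusted over the list alone (median -1.08, adjusted p = 2.3e-08, and adjusted p = 0.0356 with an estimated correlation). The chemokines CXCL8 (-2.95) and CXCL5 (-2.0), the cytokine IL1B (-2.72) and the adhesion molecule ICAM1 (-1.33) fell. Spliceosome subunits fell in 43 of 61 and rose in 4, with 45 and 4 adjusted over the list alone (median -0.48, adjusted p = 1.8e-07, and adjusted p = 0.0356 with an estimated correlation). PRPF3 (-1.82), PRPF4 (-1.35), SF3B4 (-1.26) and PRPF6 (-0.93) fell. SR proteins and kinases fell in 22 of 30 and rose in 3, also adjusted over the list alone (median -0.68, adjusted p = 8.7e-06, and adjusted p = 0.0384 with an estimated correlation), with RSRP1 (-2.02), LUC7L (-1.74) and SRRM1 (-1.18) lower and SRSF5 (0.82) higher. DNA repair genes rose in 25 of 39 and fell in 3, with 26 and 3 adjusted over the list alone (median 0.41, adjusted p = 2.7e-05, and adjusted p = 0.0398 with an estimated correlation). The damage kinase ATM (1.51), BRCA1 (1.36) and FANCI (1.31) were higher. DNA replication genes rose in 28 of 40 and fell in 4, with 30 and 5 adjusted over the list alone (median 0.48, adjusted p = 4.9e-05, and adjusted p = 0.0386 with an estimated correlation), as in LIG1 (1.78), a DNA ligase. Heat shock genes fell in 13 of 16 and 1 rose, also adjusted over the list alone (median -0.53, adjusted p = 0.00013, and adjusted p = 0.0443 with an estimated correlation), with BAG3 (-1.26) and HSPH1 (-1.20) lower. Integrated stress response genes fell in 18 of 28 and rose in 3, also adjusted over the list alone (median -0.44, adjusted p = 0.00038, and adjusted p = 0.0443 with an estimated correlation). CHAC1 (-2.02), a glutathione-degrading enzyme, and SLC3A2 (-1.96), an amino acid transporter chain, fell.

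Further lists passed with the preset correlation and not with an estimated one. snoRNA host genes fell in 19 of 25 and 1 rose, also adjusted over the list alone (median -0.65, adjusted p = 8.7e-06, and adjusted p = 0.0570 with an estimated correlation), with SNHG1 (-1.88), SNHG17 (-1.63) and ZFAS1 (-0.82) lower. Ribosomal protein genes fell in 46 of 74 with none higher, and in 47 adjusted over the list alone (median -0.26, adjusted p = 3.7e-05, and adjusted p = 0.439 with an estimated correlation), such as RPL17 (-0.98) and FAU (-0.74). snRNP assembly genes fell in 12 of 17 with none higher, also adjusted over the list alone (median -0.36, adjusted p = 0.0014, and adjusted p = 0.0570 with an estimated correlation). STRAP (-1.01) and GEMIN5 (-0.81), of the SMN complex, COIL (-0.98), of Cajal bodies, and PRMT5 (-0.78), which methylates Sm proteins, fell. Sm and LSm proteins other than SNRPD2 fell in 8 of 15 and rose in 2, also adjusted over the list alone (median -0.28, adjusted p = 0.0196, and adjusted p = 0.257 with an estimated correlation), with SNRPB (-1.02) and SNRPD1 (-0.64) lower. Pseudouridine synthases and H/ACA proteins fell in 13 of 18 and rose in 2, with 14 and 2 adjusted over the list alone (median -0.55, adjusted p = 0.0047, and adjusted p = 0.241 with an estimated correlation), among them NAF1 (-1.11), PUS1 (-0.97) and NHP2 (-0.74).

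Mitotic genes rose in 27 of 46 and fell in 10, with 28 and 10 adjusted over the list alone (median 0.28, adjusted p = 0.0037, and adjusted p = 0.257 with an estimated correlation), with CENPE (2.33) and TOP2A (1.47) higher. Hypoxia and glycolysis genes rose in 19 of 30 and fell in 3, also adjusted over the list alone (median 0.27, adjusted p = 0.0037, and adjusted p = 0.241 with an estimated correlation), with PFKFB4 (2.54) and SLC2A3 (1.81), a glucose transporter, higher. Unfolded protein response genes fell in 12 of 20 and 1 rose, with 13 and 1 adjusted over the list alone (median -0.32, adjusted p = 0.00835, and adjusted p = 0.241 with an estimated correlation), with XBP1 (-1.35) and HSPA5 (-0.83) lower. Mitochondrially encoded mRNAs fell in 10 of 13 with none higher, also adjusted over the list alone (median -0.56, adjusted p = 0.0097, and adjusted p = 0.495 with an estimated correlation), with MT-ND1 (-0.95) and MT-CO2 (-0.85) lower. Interferon response genes rose in 14 of 31 and fell in 3, also adjusted over the list alone (median 0.27, adjusted p = 0.0197, and adjusted p = 0.170 with an estimated correlation), with STAT2 (1.79) and IFIT3 (0.80) higher. Immediate early genes fell in 20 of 33 and rose in 8, also adjusted over the list alone (median -0.55, adjusted p = 0.0436, and adjusted p = 0.241 with an estimated correlation), although FOS (2.36), EGR1 (2.05) and JUN (0.92) rose. That last call was lost without Ctrl replicate 1 (adjusted p = 0.0551) or replicate 2 (0.0611), with a replicate block (0.0617) and with the GC trend removed (0.0734), with 0.0142 to 0.241 over the alternatives.

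Genes with many introns rose in HuCCT1 SNRPD2KO. The 2977 genes with 15 to 362 introns had a median log2 fold change of 0.35, with 1627 higher and 449 lower (adjusted p = 6.0e-12, and adjusted p = 0.0068 with an estimated correlation). CENPE, TPR, ATM and PRKDC (1.06), the kinase of DNA end joining, belong to this class. Genes with 1 to 4 introns had a median of -0.13 (adjusted p = 0.0178), genes with 5 to 8 introns -0.14 (adjusted p = 0.0034), and both calls held with an estimated correlation (adjusted p = 0.0125 and 0.0068). Genes with 9 to 14 introns had a median of 0.06 (adjusted p = 0.413). The 1490 genes without introns had a median of -0.19 (adjusted p = 0.0178, and adjusted p = 0.119 with an estimated correlation). No class passed in HEK293T, and the difference between the lines in this trend was not tested.

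**Figure D3:**
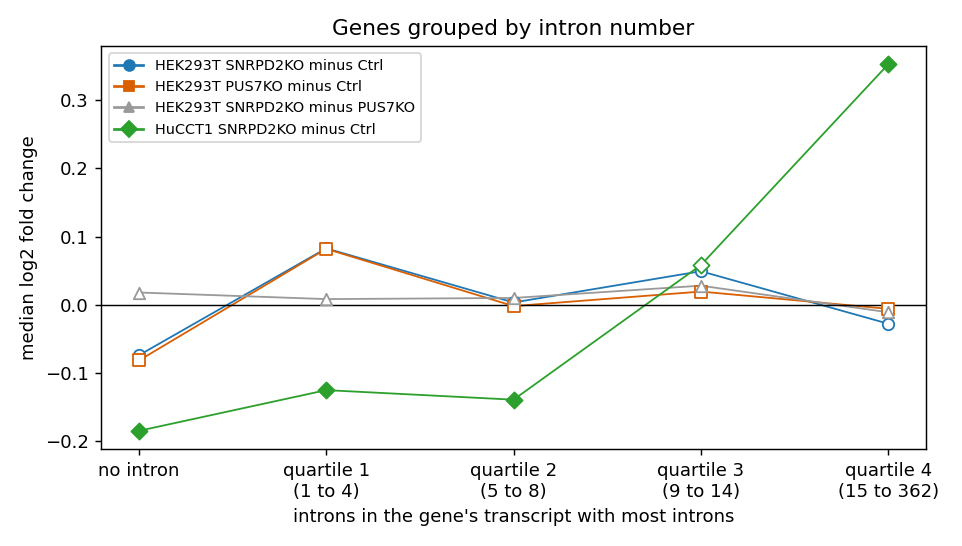
Median log2 fold change of genes by number of introns in the 4 comparisons as labelled, with filled points for classes whose adjusted p passed 0.05. In HuCCT1 the median goes from -0.19 without introns to 0.35 with 15 to 362 introns.

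Between the lines, the SNRPD2KO responses overlapped in part and differed in many genes. Of 12708 genes tested in both lines, 1601 were higher in both, where independent calls would give 1101, and 1478 lower in both, where they would give 1069. SREBF1 (1.54 in HEK293T and 2.02 in HuCCT1), the sterol response factor, HDAC6 (1.53 and 1.75), a tubulin deacetylase, TRIM65 (1.71 and 1.77), CZIB (1.86 and 1.65) and HEXD (1.56 and 1.61) rose in both. CFAP45 (-4.56 and -2.35), GDF15 (-1.66 and -1.67), CREBZF (-1.63 and -1.75), CCDC65 (-2.12 and -1.62), a ciliary protein, and VCPKMT (-1.71 and -1.47) fell in both. Another 704 were higher in HEK293T and lower in HuCCT1, and 825 the reverse, and fold changes correlated across genes with r = 0.26. In a joint fit, the response differed between the lines in 7171 of 17617 genes, 3486 higher and 3685 lower in HuCCT1. Of the 42 genes named among the strongest of either line 39 were tested for a difference, and 27 differed. Apart from the targets SNRPD2 and PUS7, they had been chosen for a large change in the same libraries, which favours a difference. Integrated stress response genes differed most as a list, with 25 of 29 members lower in HuCCT1 (median difference -1.61, adjusted p = 1.9e-15, and adjusted p = 0.00037 with an estimated correlation). Cholesterol synthesis genes went further up in HuCCT1 in 18 of 25 (median difference 1.00, adjusted p = 3.5e-08, and adjusted p = 0.0376 with an estimated correlation). Sequencing depth, the share of small noncoding RNAs and the presence of mitochondrial counts all changed together with the line. Each line's own Ctrl libraries are therefore the reference for its response.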

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

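The tests on pseudogenes, on genes next to SNRPD2, and on depth, GC content and small RNA genes for the shared response were chosen after those results were seen, and the others before.

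SNRPD2 was higher in the libraries labelled SNRPD2KO in both lines. Pseudogene reads cannot account for it, since the pseudogenes of SNRPD2 gained 0.0760% of the difference in HEK293T and 0.856% in HuCCT1. An exchange of the SNRPD2KO and Ctrl labels would give a log2 fold change above 0, which was 0.62 in HEK293T and 0.90 in HuCCT1. The exchange also predicted that SNRPD2 in HEK293T PUS7KO lies near the libraries labelled SNRPD2KO. That was met, since PUS7KO lay above Ctrl and its difference from SNRPD2KO did not pass the threshold. The deposited column heads begin with C for libraries labelled SNRPD2KO, with S for those labelled Ctrl and with P for those labelled PUS7KO. A change over the whole region could also contribute. The 10 nearest protein-coding genes had a median of 0.69 in HEK293T (percentile 97.5 of all such windows, 90.6 of those on chromosome 19). In HuCCT1 the median was 0.81 (99.5 and 97.8). Of the 10, 6 passed upward and 1 downward in HEK293T, and 8 and 1 in HuCCT1. QPCTL (1.23 and 1.92), which overlaps SNRPD2, and EML2 (1.62 and 1.13) were higher in both. DMPK (-0.76) was lower in HEK293T and FOXA3 (-1.09) in HuCCT1. These genes were singled out after their values were seen. The exchange of labels met both of its predictions in HEK293T. It and the regional change do not exclude each other, and both stay open. A knockout that leaves or raises the RNA stays open too, which gene counts do not test.

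The shared response of HEK293T SNRPD2KO and PUS7KO libraries held 6494 genes changed in the same direction in both. Thinning all libraries to the smallest total left 6129, removing the GC trend 6497, and leaving out small RNA and mitochondrial genes 6479. These are totals, and do not say that the same genes were called. With the GC trend removed, 6210 of the 8467 SNRPD2KO calls and 6738 of the 7839 PUS7KO calls returned in the same direction. The values argue against depth, GC content or a few abundant small RNAs as the whole cause, and GC content may account for part. The common Ctrl libraries entered both comparisons, and simulated counts with a common Ctrl group gave r = 0.523 against 0.90. If the SNRPD2KO and Ctrl labels were exchanged, the comparison labelled PUS7KO with Ctrl would set PUS7KO against SNRPD2KO libraries, and the shared part could come from the group common to both. A shared biological effect of both knockouts stays open as a hypothesis, as does a state of the Ctrl libraries of their own.

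The intron trend in HuCCT1 had a difference of 0.48 in median log2 fold change between genes with 15 to 362 and with 1 to 4 introns. Within 4 strata of transcript length it averaged 0.39 (95% bootstrap interval over genes 0.30 to 0.61, strata from 0.19 to 0.46). Without the lowest stratum, which held 13 genes of the top class, it averaged 0.45 (0.40 to 0.50). Within strata of GC content it averaged 0.48 (interval 0.44 to 0.52, strata from 0.39 to 0.66), and within strata of expression level 0.45 (interval 0.40 to 0.49, strata from 0.15 at the lowest level to 0.66). Transcript length, GC content and expression level are therefore argued against as the whole cause. The length of the gene with its introns was not tested. A splicing-related difference between the labelled groups may underlie the trend, as a hypothesis that counts per gene do not test.

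Each comparison of 3 with 3 libraries allows 10 splits, too few for a share under 0.05. Changed genes numbered 8467 in the real split of HEK293T SNRPD2KO and Ctrl and at most 0 in another, 7839 and 0 for PUS7KO and Ctrl, 758 and 1 for SNRPD2KO and PUS7KO, and 8591 and 0 in HuCCT1. In each of these 4 comparisons 1 of 10 splits, the real one, gave as many genes. Every other split mixes the 2 groups and puts their difference into the spread, so few calls there say little. Lists past the threshold numbered 9 in the real split and at most 7 in another, then 10 and 8, 3 and 7, and 19 and 17, in the same order. As many lists came from 1, 1, 4 and 1 of the 10 splits, so mixed groups also moved many lists under the preset correlation. For the difference between the lines, 1 of 100 drawn splits, the real one, gave as many genes (7171). Mixed splits also break up the response within a line. That share therefore argues against arbitrary labels, and cannot decide whether the responses differ between the lines. The highest other split gave 2749 genes and kept the real HEK293T groups while mixing those of HuCCT1.

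The difference between the lines in the SNRPD2KO response, HuCCT1 minus HEK293T by the interaction test, passed for 7171 genes. Of these, 1529 had been called in opposite directions in the 2 lines. CPA4 (log2 difference 7.10), UBA7 (5.52), C1orf116 (4.76), COL7A1 (4.34) and CENPE (4.14) had the largest differences upward. ARHGAP20 (-4.45), RGS16 (-4.40) and G0S2 (-4.40) were among the largest downward. EEF1B2 (-5.45) and PSME1 (-4.84) stood there too, but without HuCCT1 Ctrl replicate 1 they gave 0.36 and -0.90, neither past the threshold. EEF1B2 also missed it without HEK293T Ctrl replicate 2 or 3, HEK293T SNRPD2KO replicate 1 or any 1 of the HuCCT1 SNRPD2KO libraries (adjusted p = 0.0639 to 0.178, with 0.879 without HuCCT1 Ctrl replicate 1).

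Lists lower in the HuCCT1 response by the test of the difference, and still past the threshold with an estimated correlation, were integrated stress response genes (median difference -1.61, adjusted p = 0.00037 with an estimated correlation), snoRNA host genes (-0.77), heat shock genes (-0.52) and inflammatory signalling genes (-0.79), the last 3 at adjusted p = 0.0376. Cholesterol synthesis genes were higher (1.00, also 0.0376). Further lists passed with the preset correlation alone. Lower were snRNP assembly (-0.55, adjusted p = 0.135 with an estimated correlation), spliceosome subunits (-0.46, 0.0974), pseudouridine synthases and H/ACA proteins (-0.75, 0.0671), unfolded protein response (-0.42, 0.0671), histone (-0.66, 0.571) and ribosomal protein genes (-0.54, 0.433). Higher were mitotic (0.35, 0.139), hypoxia and glycolysis (0.58, 0.571) and DNA repair genes (0.13, 0.139), with p values of the same kind.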

How the results depend on the processing

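The GC offset, robust dispersions, thinning and most settings for intron classes were chosen after the data were seen, and the other alternatives before. Changed genes ranged over RLE, upper quartile and voom normalization, DESeq2, thinning, the GC offset, robust dispersions and an adjusted p under 0.01 from 6523 to 8553 in HEK293T SNRPD2KO against Ctrl, 5852 to 7881 in PUS7KO against Ctrl and 6842 to 8646 in HuCCT1. Tested against 1.5-fold they were 2988, 2245 and 2801, and 2 in SNRPD2KO against PUS7KO, since that test asks for a larger change. Leaving out 1 library gave 7749 to 8503, 7027 to 7623 and 7889 to 8363 in these 3 comparisons and, for the difference between the lines, 6596 to 7219. Such totals can hide a turnover of genes. With the GC offset, 6210 of 8467, 6738 of 7839 and 8036 of 8591 calls of these 3 comparisons returned in the same direction. SNRPD2 and PUS7 kept their direction and side of the threshold in all settings tried for single genes, 9 in the HEK293T comparisons with Ctrl. Those settings were fewer than the ones for the counts above.

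SNRPD2KO against PUS7KO moved most: 1292 genes without the low-count filter, 464 with the 2 groups alone in the fit, 117 with the GC offset (75 of them among the 758 in the same direction), 31 at an adjusted p under 0.01, and 22 to 1891 with 1 library left out. The cause was not tested, apart from the stricter threshold. Of 26 called genes that met the rule for named genes there, 21 lost the call in some setting. The others were WDR73, IFI6, IFIT1, RPS2 and PUS7. DESeq2 gave no test for CYFIP1 in HEK293T or for EEF1B2 and PSME1 in HuCCT1. Over all results and settings, 2435 repeats with a library left out and 1517 others kept direction and side of the threshold, while 103 and 46 lost it, 12 and 43 gained it, 53 and 45 moved (a count by over 1.5 times, or a direction that turned with no call on either side), and 1 reversed.

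Lists past the threshold numbered 1, 1, 0 and 8 with an estimated correlation against 9, 10, 3 and 19, and 19 and 18 with fry in the first 2 comparisons, which asks whether members move one way and compares no other genes. With the GC offset they were 12, 11, 10 and 18. The median of genes with 15 to 362 introns in PUS7KO against Ctrl was -0.01 and ran from -0.0264 to 0.0137 (0.0137 without PUS7KO replicate 1, 0.0106 without replicate 3) with a library left out, none past the threshold. In that comparison genes without introns passed without PUS7KO replicate 3 (-0.20, adjusted p = 0.0472). With protein-coding genes alone, genes without introns passed in SNRPD2KO against PUS7KO (adjusted p = 0.0385). The EEF1B2 difference between the lines, -5.45, ran from -6.03 to 0.36 with a library left out, and was 0.36 without HuCCT1 Ctrl replicate 1.

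Replicate numbers did not pair the samples (correlations of same-number libraries after removing group means -0.086 to 0.044 in HEK293T and -0.037 to -0.011 in HuCCT1). With a replicate block the counts were 8320, 7674, 560 and 8346, and 6933 between the lines. At this depth genes under about 10 counts were not tested, and 11 HEK293T and 18 HuCCT1 genes had 1 library at least 10-fold above the others of its group with 100 counts or more.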

Other observations

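Several lists outside the main account did not pass in HuCCT1, although single members changed. Of all genes tested there, 57.2% changed. Of 35 epithelial-mesenchymal and matrix genes 16 fell and 10 rose in SNRPD2KO (median -0.24, adjusted p = 0.126). LAMB3 (-1.97), a laminin chain, and MMP1 (-3.18) were lower, and the integrins ITGB4 (1.89) and ITGA3 (1.74) were higher. Cholangiocyte and epithelial markers fell in 11 of 24 and rose in 5 (median -0.21, adjusted p = 0.187), with LCN2 (-2.52), an iron-binding secreted protein, and KRT17 (-1.70) lower and MUC1 (1.46), a membrane mucin, higher. Apoptosis regulators fell in 15 of 31 and rose in 5 (median -0.24, adjusted p = 0.0762), with FADD (-0.87), BCL2L1 (-0.65) and the death receptor TNFRSF10B (-0.61) lower and CASP6 (1.03) higher. hnRNP proteins fell in 11 of 27 and rose in 4 (median -0.10, adjusted p = 0.264), with PCBP1 (-0.63) lower and HNRNPH3 (0.96) and PTBP3 (0.63) higher. Nonsense-mediated decay factors fell in 11 of 20 and rose in 6 (adjusted p = 0.171), with SMG8 (-1.03) lower and UPF3A (1.33) higher. p53 targets fell in 13 of 27 and rose in 8 (adjusted p = 0.407), with AEN (-1.49) and PLK3 (-1.38) lower and the repair genes XPC (1.24) and DDB2 (1.15) higher. Histone genes rose in 15 of 53 and fell in 7 (adjusted p = 0.539), with H2BC10 (0.73) and H2AC13 (0.64) higher. Abundant noncoding RNAs rose in 3 of 14 and fell in 3 (adjusted p = 0.973), with RNU4-2 (0.89) higher and RNU1-1 (-1.31) lower, and their median of 0.24 differed in sign from the mean or the test.

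In HEK293T SNRPD2KO, the nuclear noncoding RNAs NEAT1 (-2.49) and MALAT1 (-2.33) fell, and the list of abundant noncoding RNAs had 7 of 15 lower and 4 higher (median -0.54, adjusted p = 0.390). hnRNP proteins fell in 10 of 27 and rose in 7 (median -0.13, adjusted p = 0.308), with PTBP2 (-1.90), the neuronal PTB protein, lower and HNRNPAB (0.55) higher. HEK293-line markers fell in 5 of 10 and rose in 3 (median -0.30, adjusted p = 0.676), with the neurofilaments NEFM (1.20) and NEFL (0.76) higher and LIN28B (-0.73) lower. Apoptosis regulators fell in 8 of 29 and rose in 4 (median -0.09, adjusted p = 0.595), with XIAP (-1.03) lower and HRK (1.33) higher. Epithelial-mesenchymal and matrix genes rose in 9 of 30 and fell in 8 (median 0.08, adjusted p = 0.803), with COL4A2 (1.02) higher and ZEB2 (-1.12) lower. Cholesterol synthesis genes rose in 10 of 23 and fell in 3 (median 0.31, adjusted p = 0.158), and hypoxia and glycolysis genes fell in 10 of 27 and rose in 5 (median -0.37, adjusted p = 0.308). Both passed without Ctrl replicate 3 (adjusted p = 0.0471 and 0.0270). With the GC trend removed, the medians of hnRNP proteins (0.03) and matrix genes (-0.14) turned in sign, and neither list passed.

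The remaining lists in HEK293T SNRPD2KO against Ctrl did not pass: snRNP assembly (5 higher and 5 lower of 17, adjusted p = 0.803), nonsense-mediated decay factors (0 and 8 of 20, 0.107), unfolded protein response genes (9 and 4 of 20, 0.207), heat shock genes (4 and 5 of 16, 0.676), mitotic genes (8 and 15 of 46, 0.221), DNA repair genes (15 and 8 of 38, 0.390), cholangiocyte and epithelial markers (1 and 0 of 11, 0.803), snoRNA host genes (7 and 8 of 24, 0.676) and inflammatory signalling genes (2 and 3 of 14, 0.595). Median, mean and test differed in sign for snRNP assembly, pseudouridine synthases, snoRNA hosts and matrix genes there. In PUS7KO against Ctrl they differed for pseudouridine synthases, snoRNA hosts, heat shock genes and cholangiocyte markers.

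Markers of leukocytes, endothelium and fibroblasts, included to look for RNA of other cells, had 4 members tested in HEK293T. In SNRPD2KO against Ctrl 3 rose and none fell, also adjusted over the list alone (median 1.10, adjusted p = 0.0267, and adjusted p = 0.197 with an estimated correlation). HBB, a globin, had 69 counts in SNRPD2KO, 0 in Ctrl and 1 in PUS7KO. Against a floor of 3 counts over the Ctrl group, HBB was 20.5-fold higher in SNRPD2KO. The counting interval of the ratio of SNRPD2KO to Ctrl began lower, at 16.2. LUM gave 1.03 and COL1A1, which the matrix list also holds, 0.45 (not past the threshold). The call was lost without SNRPD2KO replicate 1 (adjusted p = 0.173), 2 (0.148) or 3 (0.192) and without Ctrl replicate 3 (0.249), with 3.9e-06 to 0.249 over the alternatives. In HuCCT1 2 of 4 rose and 1 fell (adjusted p = 0.407), with LUM at 1.68, COL1A1 at 0.85 and CSF1R at -0.94.

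PUS7L, a relative of PUS7 singled out after its values were seen, had raw counts of 308, 307 and 285 in the HuCCT1 SNRPD2KO libraries and 119, 166 and 154 in Ctrl. In HEK293T it had 163, 142 and 253 in SNRPD2KO, 321, 480 and 296 in PUS7KO and 278, 229 and 278 in Ctrl. The pseudogene SNRPD2P1, singled out in the same way, had 1, 0 and 0 counts in HuCCT1 SNRPD2KO and 32, 18 and 11 in Ctrl. After thinning every HEK293T library to 7944276 counts, a mean of 29494 genes had a count in Ctrl, 24487 in SNRPD2KO and 25718 in PUS7KO.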
